A study of Homo sapiens with 45 samples.

How the data were processed

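The series holds 45 arrays of total RNA from the human cell lines HEY, SKOV3 and PC3, each untransfected or transfected for 48 h with 33 nM of a precursor of miR-203a, miR-205, miR-429 or a negative control (miR-NC), with 3 arrays in each of 15 groups. Per the labels, RNA was amplified and labelled with biotin before hybridisation. The values deposited by the authors are log2 intensities after RMA, a method that corrects background, normalizes arrays and summarises probes per probe set, whose version is not given. The columns did not share 1 distribution (an order statistic spread by up to 0.99 log2 units over the arrays), so the arrays may have been normalized in more than 1 batch, and which arrays went together is not stated. Depth has no meaning for arrays, and the number of arrays limits the precision.

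Of 54675 probe sets, 41091 carried 1 gene symbol in the annotation, 1801 carried several and 11783 none, and the last 2 kinds were left out. Probe sets whose highest group mean did not exceed the median of all values (4.89) were left out, and each gene was represented by 1 probe set, its brightest on average, which gave 15599 genes. Samples were grouped by their labels, which were kept even where genes that mark a line go against them. Control probe sets and line-specific genes were used as checks only.

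All arrays entered 1 fit of 15 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 30 residual degrees of freedom, 5.24 prior degrees of freedom). Tests were two-sided and adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. Each miRNA was compared with miR-NC in its line, miR-NC with untransfected cells, and the untransfected lines with each other. The difference between lines in the response to a miRNA was tested by a moderated F-test. The labels do not say whether the 3 arrays of a group come from separate cultures, so the p-values measure only the spread between arrays. Genes called in the same direction in all 3 lines were counted beside the number that independent lists would give.

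Gene lists were written from general knowledge before the data were examined. They hold epithelial, mesenchymal and core EMT genes, EMT transcription factors, published targets of each miRNA, tight junction and desmosome genes, genes of the actin cytoskeleton and adhesion, cell cycle, interferon response, inflammatory cytokines, p53 response, unfolded protein and integrated stress response, cholesterol synthesis, TGF-beta response, miRNA machinery, ribosomal proteins, and markers of cell line identity, prostate luminal, ovarian and Mullerian, and blood cells. They were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over all lists and the 9 comparisons with miR-NC, and over all lists and the 9 differences between lines for those. As an alternative camera estimated the correlation from the data.

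The rule for naming genes was also fixed beforehand. It takes the 2 highest and 2 lowest called genes of each comparison whose arrays do not overlap between the groups, the 3 rises and 3 falls with the largest mean among genes called alike in all 3 lines, every core EMT gene, and of each other list up to 4 called members with the largest change. For the lists the text keeps to up to 2 members, of lists called in that comparison or of the published targets of the transfected miRNA, a limit set after the data were seen. For miR-NC against untransfected cells it takes the 2 highest and 2 lowest genes, and for the untransfected lines the core EMT and identity genes. Genes that mark sex were not named.

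Alternatives tried were a fit per line, the replicate number as a block, the untransfected arrays as the control, quantile normalization, array medians subtracted, no filter or a stricter filter (7.44) on dim probe sets, the mean of a gene's probe sets, leaving out probe sets that may cross-hybridise, an intensity trend with a robust prior, a 2-fold minimum, an estimated correlation, and each array left out in turn. A fit without the arrays labelled untransfected, and the other PC3 group as the control for PC3 miR-203a and PC3 miR-205, were added after seeing the data. The planned comparison of genes with and without a seed site of the miRNA was not run. The fit was tested on simulated data: with changes of 1 log2 unit added to 50 genes, 92% were recovered, with changes of 0.5 log2 units 28% and 22% in the 2 comparisons tried, and 10 of 15356 and 8 of 15354 unchanged genes were called. A shifted list was found and 0 of 19 others called, without testing the preset correlation in real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 (block) were used.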

Results

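Gene expression was measured on 45 arrays from 3 human cancer cell lines. HEY and SKOV3 are ovarian and PC3 is a prostate cancer line. Each line was left untransfected or transfected at 33 nM with a precursor of miR-203a, miR-205 or miR-429 or with a negative-control precursor (miR-NC), and RNA was taken 48 h later. These microRNAs (miRNAs) are small RNAs that lower the transcripts carrying their target sites, and they are known for holding epithelial cells in their state. The 15 groups held 3 arrays each, which limits the precision of every value. With 1 probe set per gene, 15599 genes were tested. The median of all values, 4.89, is taken as the level near background. Of 224 called results of named genes 61 had a group mean below it, so the size of such a change is only a bound, and in 9 both means lay below it. The median of an array lay between 4.49 and 4.98 log2 units. Pairs of arrays from the same transfected group correlated across probe sets at 0.986 or more, and the lowest pair was among the arrays labelled untransfected HEY, at 0.950. The study asks how cancer cell types differ in the shift from a mesenchymal to an epithelial state that miRNAs bring about.

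The labels were compared with genes that mark each line. A gene was taken as specific to a line when its lowest group mean there lay at least 3 log2 units above its highest in the other lines, over the transfected arrays only. This gave 45 genes for HEY, 84 for SKOV3 and 133 for PC3. All 36 transfected arrays scored highest for the line on their label, which their part in choosing the genes fixes in advance. None of the 9 arrays labelled untransfected did (0 of 9). On the arrays labelled untransfected HEY, 0% of the HEY-specific and 87.3% of the SKOV3-specific genes were on. On those labelled untransfected PC3, 100% of the HEY-specific and 0% of the PC3-specific genes were on. Those labelled untransfected SKOV3 had 40.9% of the PC3-specific and 31.4% of the SKOV3-specific genes on. ERBB2, which SKOV3 amplifies, averaged 12.31 ± 0.39 (SD, n = 3) on the arrays labelled untransfected HEY. Its mean was 7.60 ± 0.38 on those labelled untransfected SKOV3. HOXB13, a prostate gene, averaged 11.73 ± 0.09 on the arrays labelled untransfected SKOV3 and 4.36 ± 0.23 on those labelled untransfected PC3. The groups were kept as labelled, each miRNA was compared with miR-NC, and comparisons that involve untransfected arrays come last.

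**Figure D1:**
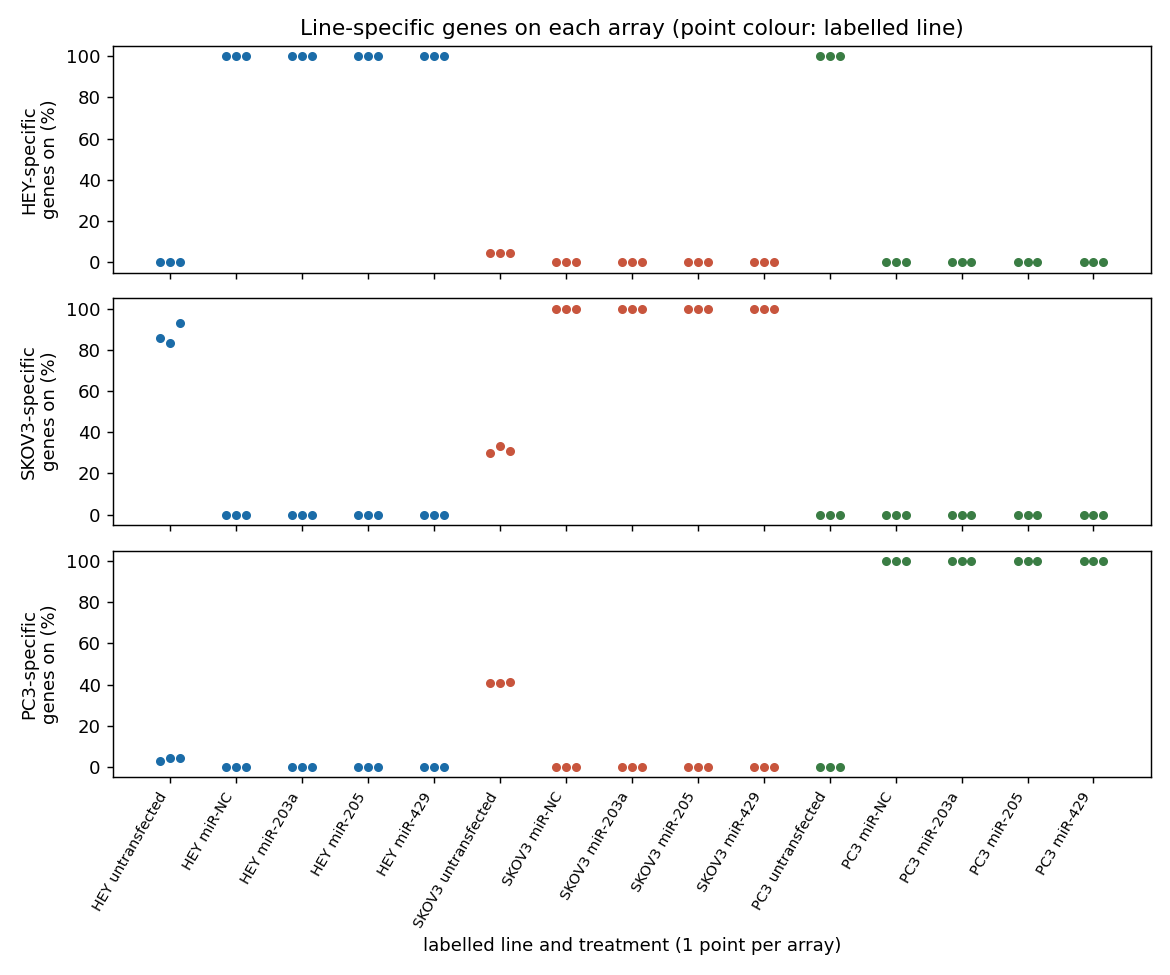
Percent of the genes specific to each line that were on, 1 panel per line, against the labelled line and treatment, with 1 point per array coloured by its labelled line. Transfected arrays show 100% in their own line's panel and 0% in the others, while the 9 arrays labelled untransfected show 33.3% or less of the genes of the line on their label.

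The control probe sets split the arrays beyond line and treatment. Against miR-NC of the same line, the probe set at the 5-prime end of GAPDH differed by 3.92 log2 units in HEY with miR-205, by -2.11 in HEY with miR-429, by 4.95 in PC3 with miR-203a and by 3.66 in PC3 with miR-205. In the other 5 miRNA groups it differed by 0.58 or less in size. The 4 groups that stood apart in this way were also the 4 with the most changed genes, so in them the miRNA and a difference in RNA, labelling or hybridisation cannot be separated from counts alone. PC3 with miR-203a and PC3 with miR-205 lay closer to each other in this probe set (9.99 ± 0.38 and 8.70 ± 0.58, SD, n = 3) than to PC3 miR-NC (5.04 ± 1.18) and were therefore also compared with each other. That comparison is not free of the control difference, since their arrays do not overlap in this probe set. The median of the tested genes moved by -0.15 in HEY and by -0.13 in PC3 with miR-429, and by -0.014 in PC3 after quantile normalization. Some changes under miR-429 in these lines are therefore also given relative to that shift, which rests on the tested genes only. Over all probe sets the median moved by 0.018 in HEY and by -0.31 in PC3, where 26 of 27 B. subtilis control probe sets were also lower.

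Few of the 13 core epithelial and mesenchymal genes were called with miR-203a in the ovarian lines, 1 higher and 2 lower in HEY and 1 lower in SKOV3. In SKOV3, SNAI2, a repressor of epithelial genes, fell by 1.30 ± 0.27 (log2, SE, n = 3 per group, adjusted p = 0.000734), while CDH1, which encodes the junction protein E-cadherin, changed by 0.39 ± 0.47. In HEY, CDH1 changed by 0.34 ± 0.47 and stayed at 3.10 ± 0.47 (SD, n = 3) log2 units, close to background, and the mesenchymal gene VIM rose by 0.52 ± 0.14 (adjusted p = 0.00766, but 0.638 with the mean of its probe sets, and not called in 2 of 6 refits without 1 array). In PC3, which already expressed CDH1 at 9.83 ± 0.19 under miR-NC, ZEB1 changed by -1.28 ± 0.13, ZEB2 by -1.41 ± 0.14 and SNAI2 by -1.08 ± 0.27, while VIM rose by 1.69 ± 0.14 on the probe set used and changed by -0.23 with the mean of its 2 probe sets. OVOL1 changed there by -0.65 ± 0.24, TWIST1 by -0.40 ± 0.15 and RAB25, from a level near background, by 1.2 ± 0.26, but the OVOL1 call was lost in 3 of 6 and the TWIST1 call in 2 of 6 refits without 1 array (adjusted p up to 0.0689 and 0.0796). With PC3 miR-205 as the control in place of miR-NC, ZEB2 (-0.91), SNAI2 (-0.76) and VIM (0.84, on the probe set used) were still called in PC3, and ZEB1 was not (-0.31, adjusted p = 0.0856). Calls of ESRP1 (-1.38 ± 0.45) and FN1 (-0.70 ± 0.23) as lower in HEY were lost in every refit without 1 of the 6 arrays, with adjusted p of 0.0633 to 0.0937 and of 0.0703 to 0.124. The SE is pooled over all groups, and their SDs there were 0.14 or less.

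The published targets of miR-203a, a list of 18 tested genes fixed before the data were examined, fell most clearly in SKOV3. Their median there was -0.51 log2 units (camera adjusted p = 1.96e-08, or 0.0621 with an estimated correlation), with 9 genes lower and 0 higher over all genes, and 11 lower and 2 higher adjusted over the list alone. SRC changed by -1.89 ± 0.25 and RAPGEF1 by -1.87 ± 0.22. In HEY the median was -0.27 (adjusted p = 0.00621, or 0.671 with an estimated correlation), with 6 genes lower, and 7 lower and 1 higher adjusted over the list alone. LASP1 changed by -1.01 ± 0.13 and SOCS3 by -1.05 ± 0.23 in HEY. In PC3 the list had 9 genes lower and 5 higher on either count, a median of -0.40 and an adjusted p of 0.341. CKAP4, which is on the list, rose there by 1.42 ± 0.12, but by 0.15 against PC3 miR-205.

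The list of cholesterol synthesis shifted up with miR-203a in both ovarian lines, though most of its members were not called. The median of 19 genes was 0.37 in HEY (adjusted p = 2.12e-05, or 0.0173 with an estimated correlation), with 7 higher and 1 lower, and 0.39 in SKOV3 (adjusted p = 0.00151, or 0.0971 with an estimated correlation), with 8 higher and 1 lower. EBP rose by 1.00 ± 0.24 in HEY and IDI1 by 0.94 ± 0.12 in SKOV3, while INSIG1, the feedback inhibitor on the list, fell by 1.70 ± 0.11 in SKOV3. Inflammatory cytokines shifted down in HEY, with a median of -0.58 over 20 genes, 9 lower and 0 higher (adjusted p = 5.39e-06, or 0.274 with an estimated correlation). CXCL1 changed by -1.42 ± 0.16 there and CXCL8 by -1.38 ± 0.32. Interferon-response genes in HEY had a median of -0.23 (adjusted p = 0.00991, or 0.863 with an estimated correlation), with 7 of 40 lower and 0 higher, IFIT1 at -2.31 ± 0.29 and IFIT3 at -1.40 ± 0.16.

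In HEY with miR-203a, 2052 of 15599 genes changed (908 higher, 1144 lower, 384 at least 2-fold). A separate fit per line called 1051 there. In SKOV3 the count was 1863, with 1102 higher, 761 lower and 362 at least 2-fold. In PC3 it was 8754, with 4847 higher, 3907 lower and 3260 at least 2-fold. Against PC3 miR-205, 3862 genes differed in PC3 miR-203a, 1855 of them higher. The largest changes in HEY were ZBED2, higher by 3.20 ± 0.25, ANKRD1, higher by 2.87 ± 0.29, MOBP, at -3.42 ± 0.31, and C16orf54, at -3.19 ± 0.21, each with 1 of its 2 group means near background. In SKOV3, ITGB8 rose by 3.22 ± 0.30 and DDAH1 by 3.14 ± 0.12, and MAP3K20 changed by -2.77 ± 0.13 and PAPSS2 by -2.60 ± 0.17. In PC3, RPL29 rose by 4.83 ± 0.25 and RPL18 by 4.64 ± 0.21, against 1.01 and 1.37 relative to PC3 miR-205. THSD7A changed there by -3.69 ± 0.20 and SLC6A16 by -3.59 ± 0.32, or by -1.34 and -1.09 relative to PC3 miR-205, both to levels near background (3.25 and 4.54).

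Several lists moved in PC3 with miR-203a, 1 of the 4 groups with their own control levels. Ribosomal protein genes had a median of 1.83 (adjusted p = 8.01e-13, or 0.407 with an estimated correlation), with RPS9 higher by 4.16 ± 0.33 against miR-NC and by 0.96 against PC3 miR-205. The epithelial list had a median of 0.90 (adjusted p = 0.000331, or 0.391 with an estimated correlation), with 26 of 45 genes higher and 4 lower over all genes, and 27 and 4 adjusted over the list alone. KRT7 rose by 3.50 ± 0.19 and SPINT1 by 3.44 ± 0.36. Against PC3 miR-205 the median of the epithelial list differed by 0.22, with 7 genes called higher and 2 lower, and no list test was run for this comparison. Genes of the unfolded protein and integrated stress response had a median of 0.60 (adjusted p = 0.0368, or 0.88 with an estimated correlation), with 12 of 25 higher and 1 lower, SDF2L1 higher by 2.10 ± 0.15 and ATF4 by 1.89 ± 0.18. Against PC3 miR-205, ATF4 differed by 0.033 and SDF2L1 by 0.46.

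The epithelial list did not pass the threshold with miR-203a in HEY (median 0.054, adjusted p = 0.341) or in SKOV3 (0.097, adjusted p = 0.35). The mesenchymal list passed it in no line, with medians of 0.11 in HEY, 0.009 in SKOV3 and -0.054 in PC3. For SKOV3 its mean (-0.085) and the direction of the test were negative against the positive median, and for PC3 the mean was 0.17 against a negative median and test.

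ZEB1, a repressor of E-cadherin and a published target of miR-205, was lower with miR-205 in all 3 lines. ZEB1 changed by -1.81 ± 0.13 (log2, SE, n = 3 per group, adjusted p = 1.55e-14) in HEY, by -1.38 ± 0.13 (adjusted p = 2.67e-10) in SKOV3 and by -0.98 ± 0.13 (adjusted p = 1.04e-07) in PC3. EPCAM, an epithelial surface protein, rose in SKOV3 by 2.19 ± 0.26, from 7.12 ± 0.51 to 9.31 ± 0.11 (SD, n = 3), while CDH1 went there from 4.03 ± 0.09 to 4.78 ± 0.15, by 0.75 ± 0.47, without passing the threshold (adjusted p = 0.26). The SE is pooled over all groups, and the arrays labelled untransfected HEY had an SD of 2.09 for CDH1. In a fit without the arrays labelled untransfected, added after the data were seen, this change passed the threshold (adjusted p = 0.0173), as it did in a separate fit per line (0.00763). SNAI2 rose in SKOV3 by 1.02 ± 0.27 and CDH2 by 0.69 ± 0.24, though the CDH2 call was lost in 5 of 6 refits without 1 array (adjusted p of 0.0426 to 0.126). In HEY, ZEB2 changed by -1.92 ± 0.14 and TWIST1 by -1.81 ± 0.15, yet CDH1 and EPCAM stayed at 2.90 ± 0.46 and 3.83 ± 0.10, near background, and ESRP1 changed by -1.52 ± 0.45. VIM rose there by 1.37 ± 0.14 on the probe set used and changed by -0.65 with the mean of its probe sets. In PC3, ZEB2 changed by -0.50 ± 0.14 and EPCAM rose by 0.70 ± 0.26, a call lost in 2 of 6 refits (adjusted p up to 0.0715). RAB25 differed by 0.76 ± 0.26 with both means near background, a call lost in 1 of 6 refits, and VIM rose by 0.85 ± 0.14 on the probe set used and changed by -0.37 with the mean. With PC3 miR-203a as the control, ZEB1 in PC3 differed by 0.31, so its fall was shared by both PC3 groups.

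As a list, the 19 tested published targets of miR-205 shifted down in SKOV3 with a median of -0.44 (adjusted p = 9.08e-05, and 0.0119 with an estimated correlation), though 10 were not called. There 8 genes were lower and 1 higher, both over all genes and adjusted over the list alone, and E2F1 fell by 1.79 ± 0.23. In HEY the median was -0.66 without passing the threshold (adjusted p = 0.0872), with 11 genes lower and 5 higher on either count. PRKCE had the largest change of the list in HEY, at -3.82 ± 0.15, and ITGA5 rose by 2.11 ± 0.17. In PC3 the median was -0.071 (adjusted p = 0.603), with 6 genes lower and 6 higher on either count. SRC rose there by 1.58 ± 0.25 and ITGA5 by 1.15 ± 0.17, and both were also higher than with PC3 miR-203a, by 1.28 and 0.77.

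Interferon-response genes rose with miR-205 in PC3. Of 40 genes on that fixed list 39 were higher, over all genes and adjusted over the list alone, with a median of 3.59 (adjusted p = 3.11e-32, and 0.00511 with an estimated correlation). OASL rose by 6.32 ± 0.25 and the chemokine CXCL10 by 6.07 ± 0.30, from means of 4.66 and 4.29 that lie below the median of all values (4.89), so their folds are not given. The list also lay lower in PC3 miR-203a than in PC3 miR-205, with a median of -2.75 and 39 of 40 genes lower. Its median was -0.14 in HEY (adjusted p = 0.614) and -0.004 in SKOV3 (adjusted p = 0.915), and the difference between lines was 3.79 for PC3 minus HEY (adjusted p = 3.07e-28, and 0.00661 with an estimated correlation) and 3.75 for PC3 minus SKOV3 (adjusted p = 1.51e-31, and 0.00592). Inflammatory cytokines rose in PC3 with a median of 0.90, 15 of 20 higher and 1 lower (adjusted p = 0.00621, or 0.686 with an estimated correlation). CCL20 was higher by 2.07 ± 0.27 and NFKBIA by 1.86 ± 0.21, or by 3.32 and 0.32 against PC3 miR-203a. Genes of the unfolded protein and integrated stress response had a median of 1.04, with 22 of 25 higher and 1 lower (adjusted p = 2.12e-05, or 0.686 with an estimated correlation), with ATF3 higher by 2.32 ± 0.38 and DDIT4 by 2.13 ± 0.26.

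The list of miRNA machinery shifted up in SKOV3 with miR-205, with a median of 0.19 (adjusted p = 0.0246, or 0.407 with an estimated correlation), though only 5 of its 12 genes were called higher and 1 lower. After quantile normalization its median was 0.048 and the call was lost (adjusted p = 0.0998), as it was in a separate fit per line (0.108). DICER1 was higher by 2.22 ± 0.15 and TNRC6A by 1.81 ± 0.14. Ribosomal protein genes had medians of 0.97 in HEY (adjusted p = 3.09e-05, or 0.863 with an estimated correlation) and 1.31 in PC3 (adjusted p = 2.14e-10, or 0.497), both groups with their own control levels. RPL18 rose by 3.50 ± 0.21 in HEY and by 3.27 ± 0.21 in PC3, where it lay 1.37 higher with miR-203a. The epithelial list had a median of 0.64 in PC3 (adjusted p = 0.00267, or 0.497 with an estimated correlation), with 25 of 45 genes higher and 5 lower over all genes, and 26 and 6 adjusted over the list alone. KRT8 rose there by 2.99 ± 0.18 and KRT7 by 2.80 ± 0.19, but against PC3 miR-203a they differed by -0.28 and -0.70. The epithelial list passed the threshold neither in HEY (median 0.24, adjusted p = 0.68) nor in SKOV3 (0.052, adjusted p = 0.341). The mesenchymal list passed it in no line, with medians of 0.012 in HEY, 0.21 in SKOV3 and 0.14 in PC3.

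In HEY with miR-205, 10259 genes changed against miR-NC (5238 higher, 5021 lower, 5186 at least 2-fold). In SKOV3 it was 4001 (2627 higher, 1374 lower, 768 at least 2-fold), or 2012 higher and 1778 lower after quantile normalization. In PC3 it was 7548 (4472 higher, 3076 lower, 2555 at least 2-fold). The largest rises in HEY were KRT18 at 4.18 ± 0.17 and TIMM50 at 4.17 ± 0.21, and the largest falls were FBXO32 at -4.85 ± 0.19, to a level near background (4.11), and VMP1 at -4.36 ± 0.29. In SKOV3, PKIA rose by 4.19 ± 0.49 and ASPH by 4.17 ± 0.14, and C9orf40 changed by -3.16 ± 0.15 and RPIA by -2.62 ± 0.14. In PC3 the largest falls were SLC26A5-AS1 at -3.79 ± 0.21 and PCDHB16 at -3.22 ± 0.35, both to levels near background (4.05 and 3.29). Against PC3 miR-203a they differed by -0.99 and 0.20.

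MiR-429 switched on E-cadherin in SKOV3. CDH1 rose by 4.56 ± 0.47 (log2, SE, n = 3 per group, adjusted p = 1.46e-09), from 4.03 ± 0.09, below the median of all values, to 8.59 ± 0.17 (SD, n = 3), so its fold is not given. EPCAM rose by 4.41 ± 0.26 from 7.12 ± 0.51, or 21.3-fold. ZEB1 changed in the same cells by -2.15 ± 0.13 and the mesenchymal matrix gene FN1 by -1.69 ± 0.23, while VIM changed by -0.13 ± 0.14. ZEB2 changed there by -0.44 ± 0.14, with both means near background and the call lost in 3 of 6 refits without 1 array. In HEY, ZEB1 changed by -2.22 ± 0.13 and ZEB2 by -2.52 ± 0.14, or by -2.06 and -2.37 relative to the shift of all tested genes, and FN1 by -1.61 ± 0.23, but CDH1 changed by 0.52 ± 0.47 and stayed at 3.28 ± 0.45. SNAI2 rose in HEY by 1.16 ± 0.27 (adjusted p = 0.000426) and VIM by 1.47 ± 0.14 (adjusted p = 2.42e-11, but 0.184 with the mean of its probe sets). OVOL1 (4.04 to 3.13), GRHL2 (2.61 to 3.27) and EPCAM (3.48 to 4.26) were called there with both means near background, so no direction is read from them. TWIST1 changed by -0.39 ± 0.15 in HEY, a call lost in 4 of 6 refits (adjusted p up to 0.0647). In PC3, which already expressed CDH1 and EPCAM, the epithelial transcription factor GRHL2 rose by 2.06 ± 0.15 and FN1 changed by -1.59 ± 0.23, or by 2.19 and -1.46 relative to the shift. SNAI2 changed there by -1.08 ± 0.27 and OVOL1 by -1.09 ± 0.24. ZEB1 changed in PC3 by -0.62 ± 0.13 and, with array medians subtracted, no longer passed the threshold. EPCAM rose by 0.67 ± 0.26 in PC3, but the call was lost in every refit without 1 of the 6 arrays (adjusted p of 0.0577 to 0.0698), and the HEY call was lost without HEY miR-429 replicate 1 (adjusted p = 0.0991).

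**Figure D2:**
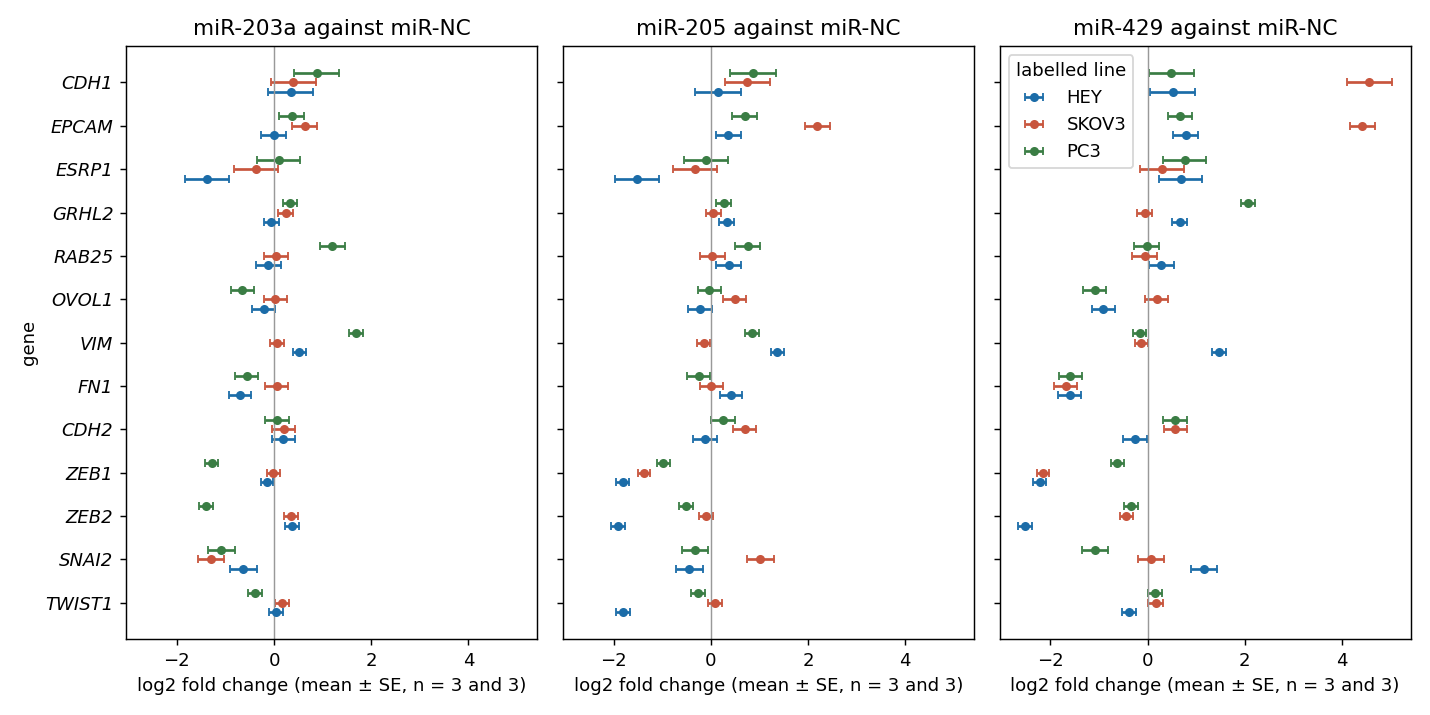
Log2 fold change against miR-NC, mean ± SE from 3 and 3 arrays, of 13 epithelial and mesenchymal genes fixed before the data were examined, with 1 panel per miRNA and 1 colour per labelled line. CDH1 and EPCAM moved furthest in SKOV3 with miR-429 (4.56 and 4.41), and ZEB1 fell with miR-205 and miR-429 in all 3 lines.

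The epithelial list as a whole rose with miR-429 in SKOV3, with a median of 0.54 (adjusted p = 2.75e-08, and 0.0457 with an estimated correlation). Of its 45 genes 22 were higher and 0 lower over all genes, and 24 and 0 adjusted over the list alone. Of 28 tight junction and desmosome genes 14 rose and 0 fell (median 0.47, adjusted p = 4.37e-06, and 0.0119 with an estimated correlation). PATJ was higher by 2.08 ± 0.21 and PKP2 by 1.92 ± 0.18. The mesenchymal list fell slightly in SKOV3, with a median of -0.10 (adjusted p = 0.0368, or 0.88 with an estimated correlation) and 10 of 51 genes lower against 5 higher on either count. Without SKOV3 miR-NC replicate 2 its median was -0.029 (adjusted p = 0.0512). LOX, on that list, fell by 3.18 ± 0.30, to a level near background (4.46). In HEY the epithelial list had a median of 0.38, or 0.54 relative to the shift (adjusted p = 0.00991, or 0.644 with an estimated correlation), with 17 genes higher and 9 lower on either count. HEY miR-429 has its own control levels. KRT18 was higher there by 3.45 ± 0.17 (4.18 with miR-205, also set apart) and SPINT2 by 2.59 ± 0.16. In PC3 its median was 0.28, or 0.40 relative to the shift (adjusted p = 0.0804), with 13 genes higher and 9 lower on either count. Tight junction and desmosome genes in PC3 had a median of 0.26 (adjusted p = 0.0368, or 0.407 with an estimated correlation), PPL rose by 1.06 ± 0.27 and CLDN3 fell by 1.21 ± 0.24. That list call was lost after quantile normalization (adjusted p = 0.0727), with array medians subtracted (0.0778), with a stricter filter (0.125) and in 2 of 6 refits without 1 array. The mesenchymal list did not pass the threshold in HEY (median -0.18, or -0.03 relative to the shift) or in PC3 (-0.34, or -0.21 relative to the shift). After quantile normalization its PC3 median was -0.20 (adjusted p = 0.0408). Subtracting array medians, which moves all genes of an array alike, gave 0.070.

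The 24 tested published targets of miR-429 had negative medians in all 3 lines. In SKOV3 the median was -0.36 (adjusted p = 1.35e-05, or 0.319 with an estimated correlation), with 13 genes lower and 2 higher on either count. WIPF1 changed there by -2.40 ± 0.20 and SEC23A by -2.33 ± 0.15. In HEY the median was -0.69, or -0.54 relative to the shift (adjusted p = 0.0368, or 0.863 with an estimated correlation), with 14 genes lower over all genes and 16 adjusted over the list alone, against 3 higher on either count. In PC3 it was -0.35, or -0.23 relative to the shift (adjusted p = 0.0804), with 13 genes lower over all genes and 14 adjusted over the list alone, against 3 higher on either count. After quantile normalization the PC3 median was -0.35 (adjusted p = 0.000344). Subtracting array medians gave 0.054 (adjusted p = 0.146). Of the list, WIPF1 changed most in PC3, at -2.57 ± 0.20. Inflammatory cytokines shifted down in SKOV3 with a median of -0.42, 6 of 20 lower and 0 higher (adjusted p = 0.000985, or 0.55 with an estimated correlation). CXCL2 changed by -1.99 ± 0.47 and CXCL8 by -1.51 ± 0.32. Ribosomal protein genes in HEY had a median of 0.58 (adjusted p = 1.20e-06, or 0.793 with an estimated correlation), with RPL18 at 2.18 ± 0.21 and RPL35 at 2.13 ± 0.14. This list passed only in the 4 groups with their own control levels.

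In HEY with miR-429, 8854 genes changed against miR-NC (3279 higher, 5575 lower, 3412 at least 2-fold). In SKOV3 it was 3443 (2323 higher, 1120 lower, 666 at least 2-fold), or 1837 higher and 1596 lower after quantile normalization. In PC3 it was 7175 (2544 higher, 4631 lower, 1602 at least 2-fold), or 6363 higher and 1895 lower with array medians subtracted. The largest rises in HEY were BRD2 at 4.61 ± 0.22 and LMO7 at 4.48 ± 0.21, and the largest falls were SNTG2-AS1 at -4.38 ± 0.34 and SLC44A5 at -4.06 ± 0.22, both to levels near background (3.32 and 2.81). In SKOV3 the largest rises were those of CDH1 and EPCAM, and OSTM1 fell by 3.41 ± 0.13. In PC3, ITGB8 rose by 2.12 ± 0.30, and GPM6A changed by -3.28 ± 0.29 and DACH1 by -3.14 ± 0.22, both to levels near background (3.79 and 2.22).

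The difference between lines, which the title of the series asks about, was tested directly. The response differed between the lines for 7009 genes (44.9%) with miR-203a, 10862 (69.6%) with miR-205 and 10375 (66.5%) with miR-429. For CDH1 with miR-429 the highest and the lowest response, in SKOV3 and PC3, lay 4.07 log2 units apart (adjusted p = 1.03e-06), and for EPCAM 3.74 apart (adjusted p = 4.21e-11). GRHL2 differed by 2.12 with miR-429 (adjusted p = 8.90e-10), with its rise in PC3. VIM differed by 1.63 with miR-203a (adjusted p = 4.60e-08), with its rise in PC3, which turned to -0.23 with the mean of its probe sets. TWIST1 differed by 1.89 with miR-205 (adjusted p = 9.63e-10), with its fall in HEY. These counts include whatever sets apart the 4 groups with their own control levels. In transfected SKOV3 the 3-prime minus the 5-prime probe set of ACTB averaged -0.08 to 0.06, against 5.20 to 9.35 in transfected HEY and PC3. Every difference from SKOV3 includes this split too.

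For the epithelial list as a whole 2 of 9 differences between lines passed the threshold. With miR-429 the difference was 0.16 for SKOV3 minus HEY (adjusted p = 0.981), -0.11 for PC3 minus HEY (0.561) and -0.69 for PC3 minus SKOV3 (0.0604). The last lies close to the threshold and passed it after quantile normalization (-0.52, adjusted p = 0.0124), with array medians subtracted (-0.32, 0.00937), with an intensity trend and robust prior (0.0469) and in 3 of 12 refits without 1 array. With miR-203a it was 0.95 for PC3 minus HEY (adjusted p = 0.0009, or 0.745 with an estimated correlation) and 0.67 for PC3 minus SKOV3 (0.00677, or 0.859). With miR-205 it passed the threshold in no pair, with adjusted p of 0.0754, 0.212 and 0.974. The mesenchymal list differed only with miR-203a for SKOV3 minus HEY, by -0.13 (adjusted p = 0.0279, or 0.999 with an estimated correlation). Without SKOV3 miR-203a replicate 3 or HEY miR-NC replicate 2 that difference no longer passed (adjusted p = 0.0585 and 0.0739). The published targets of miR-203a lay lower in SKOV3 than in HEY, by -0.26 (adjusted p = 0.0102, or 0.879 with an estimated correlation).

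Some genes changed alike in every line against miR-NC, whose own effect was not tested. With miR-203a, 193 genes were higher and 224 lower in all 3 lines, against 19.9 and 14 for independent lists. Without the arrays labelled untransfected, 629 genes changed alike. RASSF6 changed by -1.34 ± 0.18 in HEY (both means near background), by -1.99 ± 0.18 in SKOV3 and by -2.48 ± 0.18 in PC3. SP4 changed by -1.44, -1.94 and -2.28 in the same order, and LOX by -1.50, -2.21 and -1.94. In PC3 all 3 also lay lower than with miR-205, by -2.05, -1.20 and -1.69. ITGB8 (with miR-429 too), ARPC4 and PKIA rose in all 3 lines, but in PC3 none of the 3 was called against PC3 miR-205 (-0.003, 0.096 and -0.25). PKIA in HEY lost its call in all 6 refits without 1 array (adjusted p of 0.055 to 0.0685), and in PC3 without replicate 3 of PC3 miR-203a or miR-NC (0.0531 and 0.0601). Its SE (0.489) is pooled over all groups, against SDs of 0.07 or less in HEY.

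With miR-205, 432 genes were higher and 390 lower in all 3 lines, against 252.9 and 87.2 for independent lists. Among the higher genes HEY and PC3 shared 2942 against 1501.7, while HEY and SKOV3 shared 678 against 882.1 and SKOV3 and PC3 803 against 753.1. Most of the excess thus lies in HEY and PC3, both groups with their own control levels. C9orf40 changed by -2.29 ± 0.15 in HEY, by -3.16 ± 0.15 in SKOV3 and by -2.16 ± 0.15 in PC3. TMEM170B changed by -3.70, -1.46 and -2.16, and KAT2B by -3.22, -1.74 and -1.96. All 3 also lay lower than with PC3 miR-203a, by -1.57, -1.63 and -0.98. NARF, MRPL27 and KRT7 rose in every line, but relative to PC3 miR-203a they lay lower in PC3, by -0.54, -0.42 and -0.70. With miR-429, 247 genes were higher and 315 lower in all 3 lines, against 79.6 and 118.8 for independent lists, though HEY and PC3 shared 1578 lower genes against 1655.1. OSTM1 changed by -3.02 ± 0.13 in HEY, by -3.41 ± 0.13 in SKOV3 and by -1.89 ± 0.13 in PC3. WIPF1 changed by -2.20, -2.40 and -2.57, and GPM6A, with a mean near background in each line and both in SKOV3, by -2.20, -1.59 and -3.28. ITGB8 rose by 0.99, 3.78 and 2.12, MAP7 by 1.32, 3.57 and 1.38, and ASPH by 0.83, 4.14 and 1.09. For ASPH the mean of its probe sets gave -0.44 in HEY.

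Across genes, which are not independent replicates, the changes of 2 lines with the same miRNA correlated at 0.38 (HEY and SKOV3), 0.43 (HEY and PC3) and 0.13 (SKOV3 and PC3) for miR-203a. Spearman's rho was 0.34, 0.45 and 0.11. For miR-205 Pearson's r was -0.036, 0.55 and 0.093 (rho -0.054, 0.57 and 0.081), and for miR-429 it was 0.089, 0.036 and 0.38 (rho 0.070, 0.002 and 0.38). The highest value of all 27 pairs of miRNA responses in different lines joined different miRNAs, PC3 miR-203a and HEY miR-205, at 0.64 (rho 0.64).

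**Figure D3:**
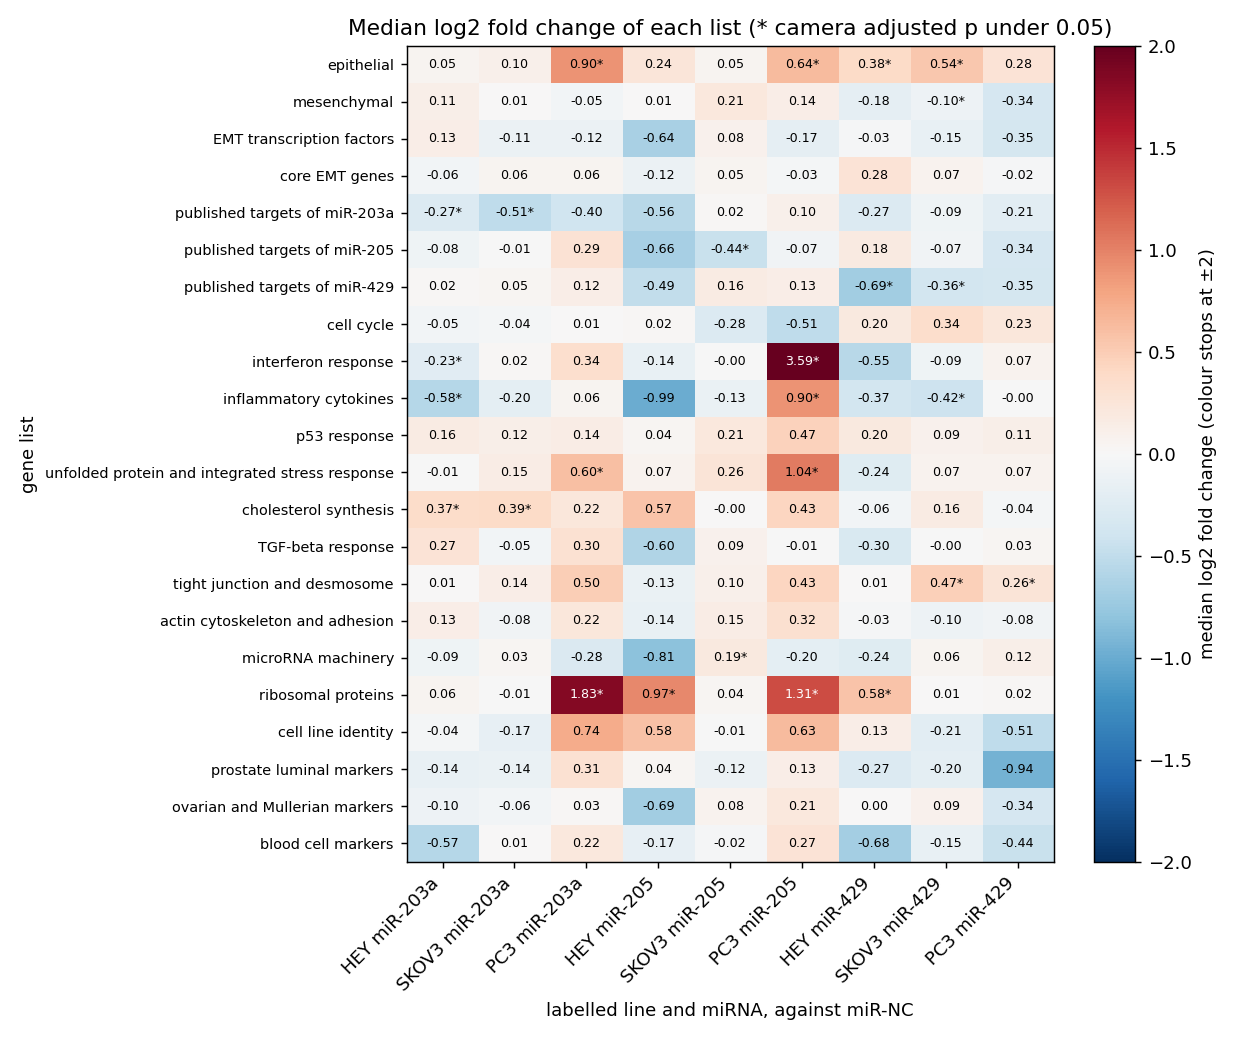
Median log2 fold change against miR-NC of each fixed gene list (vertical axis) for each labelled line and miRNA (horizontal axis), with colour for the median, which stops at ±2, and a star for a camera adjusted p under 0.05. The interferon list in PC3 with miR-205 stands out at 3.59, and the epithelial list carries its lowest adjusted p, 2.75e-08, in SKOV3 with miR-429.

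The other fixed lists passed the threshold in no comparison of a miRNA with miR-NC in the fit of all arrays. Under some alternatives the cell cycle and the actin cytoskeleton and adhesion lists did, the latter in PC3 with miR-429 after quantile normalization (median -0.15, adjusted p = 0.0232). Cell cycle genes had medians from -0.51 (PC3 miR-205) to 0.34 (SKOV3 miR-429), with a lowest adjusted p of 0.0562. Without the arrays labelled untransfected that list did pass in PC3 with miR-205 (adjusted p = 1.9e-05), SKOV3 with miR-205 (0.000156), and with miR-429 in HEY (0.00464), SKOV3 (1.9e-05) and PC3 (5.35e-05). The p53 response ranged from 0.039 to 0.47 (lowest adjusted p 0.223), the TGF-beta response from -0.60 to 0.30 (0.151) and genes of the actin cytoskeleton and adhesion from -0.15 to 0.32 (0.0562). The EMT transcription factors (EMT stands for epithelial-to-mesenchymal transition) ranged from -0.64 in HEY with miR-205 to 0.13 (0.144). The 13 core EMT genes ranged from -0.12 to 0.28 (0.62). Lists of cell line identity (-0.51 to 0.74, lowest adjusted p 0.254), prostate luminal (-0.94 to 0.31, 0.549), ovarian and Mullerian (-0.69 to 0.21, 0.747) and blood cell markers (-0.68 to 0.27, 0.47) were kept as controls. Median and mean had opposite signs in 23 of 198 list shifts, none of them past the threshold. Examples are the actin cytoskeleton and adhesion list in HEY with miR-205 (-0.15 and 0.35), core EMT genes in HEY with miR-429 (0.28 and -0.18) and blood cell markers in PC3 with miR-205 (0.27 and -0.11).

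The comparison of miR-NC with untransfected cells asks what transfection with the control precursor does by itself. The arrays labelled untransfected lacked the genes of the line on their label, so no effect of transfection can be read from it. Of the genes that follow all but S100A4 had 1 group mean near background, so their differences are bounds. INHBA was 10.22 ± 0.11 log2 units higher in HEY miR-NC than on the arrays labelled untransfected HEY, ARMCX1 was 8.85 ± 0.18 higher, and S100A4 differed by -8.77 ± 0.16. SPP1 was 8.67 ± 0.17 and NNMT 8.56 ± 0.13 higher in SKOV3 miR-NC than on the arrays labelled untransfected SKOV3. The prostate gene PRAC1 and AGR2 differed by -9.57 ± 0.18 and -9.01 ± 0.18. TSPYL5 was 9.80 ± 0.19 and CALB1 8.93 ± 0.21 higher in PC3 miR-NC than on the arrays labelled untransfected PC3, while UCHL1 differed by -8.76 ± 0.15 and ECSCR by -8.12 ± 0.22. These comparisons called 13002 genes in HEY (7575 higher, 5427 lower), 11345 in SKOV3 (6539 higher, 4806 lower) and 12019 in PC3 (6765 higher, 5254 lower). After quantile normalization the SKOV3 split was 5436 higher and 6120 lower. The median of the tested genes moved in these comparisons by 0.29, 0.14 and 0.15, and by -0.045, -0.070 and 0.016 after quantile normalization.

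Comparing the untransfected lines was meant to give their starting state. Between the arrays labelled untransfected SKOV3 and HEY, 8275 genes differed (4060 higher on those labelled SKOV3, 4215 lower). Between those labelled PC3 and HEY it was 11608 (6355 higher, 5253 lower), and between those labelled PC3 and SKOV3 11945 (6426 higher, 5519 lower). CDH1 averaged 2.93 ± 0.10 (SD, n = 3) on the arrays labelled untransfected PC3, 10.13 ± 0.23 on those labelled SKOV3 and 8.12 ± 2.09 on those labelled HEY. ZEB2 averaged 8.74 ± 0.13, 2.52 ± 0.24 and 2.41 ± 0.18 in the same order. CDKN2A was 11.79 ± 0.08 on the arrays labelled SKOV3 and 4.17 ± 0.03 on those labelled PC3, and PAX8 was 10.94 ± 0.27 on those labelled PC3 and 8.43 ± 0.17 on those labelled SKOV3. In the miR-NC groups CDH1 averaged 2.76 ± 0.37 in HEY, 4.03 ± 0.09 in SKOV3 and 9.83 ± 0.19 in PC3, and ZEB1 averaged 11.55 ± 0.01, 9.72 ± 0.07 and 10.96 ± 0.19.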

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

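Only the test of the transfected miRNA's own effect was written before its result was seen. The tests of exchanged labels, of another labelling or hybridisation, of transfection itself, of sets of arrays, of the interferon genes and of other splits of the arrays were chosen after. Named genes and lists are given here because the test of the difference between lines passed the threshold, and control probe sets because they showed signal in some arrays and not in others.

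The response to miR-203a differed between the 3 lines for genes named in the text, by these log2 distances from the lowest to the highest response: ZBED2 3.42, ANKRD1 2.09, MOBP 3.36, C16orf54 3.14, ITGB8 2.25, DDAH1 2.82, MAP3K20 1.88, PAPSS2 2.13, RPL29 4.70, RPL18 4.62, THSD7A 3.67 and SLC6A16 3.37. With miR-203a, further distances were ARPC4 2.15, RASSF6 1.14, SP4 0.84, RAB25 1.32, VIM 1.63, ZEB1 1.27, ZEB2 1.77, KRT7 3.58, SPINT1 3.48, LASP1 0.86, SRC 2.19 and RAPGEF1 2.56. With miR-203a, to these add CKAP4 1.34, IFIT1 2.35, IFIT3 0.67, CXCL1 1.39, CXCL8 1.50, SDF2L1 1.86, ATF4 1.52, EBP 2.45, STARD4 0.83, INSIG1 1.37, IDI1 1.02 and RPS9 4.18. The highest adjusted p of these genes was 0.0477, for IFIT3.

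The response to miR-205 differed likewise, by these log2 distances: KRT18 3.77, TIMM50 4.0, FBXO32 4.43, VMP1 4.17, PKIA 3.73, ASPH 3.77, C9orf40 0.99, RPIA 1.32, OASL 6.28, CXCL10 6.22, SLC26A5-AS1 4.10 and PCDHB16 4.17. With miR-205, further distances were NARF 2.30, KRT7 2.32, MRPL27 3.21, TMEM170B 2.24, KAT2B 1.48, EPCAM 1.84, VIM 1.51, ZEB1 0.84, ZEB2 1.81, SNAI2 1.46, TWIST1 1.89 and KRT8 2.62. With miR-205, to these add PRKCE 3.75, ITGA5 2.08, E2F1 1.41, SRC 1.54, CCL20 5.04, NFKBIA 2.32, ATF3 3.06, DDIT4 2.76, DICER1 3.09, TNRC6A 2.42, RPL18 3.41 and RPS9 3.44. The highest adjusted p of these genes was 0.00163, for SNAI2.

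The response to miR-429 differed likewise, by these log2 distances: BRD2 4.78, LMO7 4.55, SNTG2-AS1 4.71, SLC44A5 4.11, CDH1 4.07, EPCAM 3.74, OSTM1 1.52, LOX 1.87, ITGB8 2.79, GRHL2 2.12, GPM6A 1.70 and DACH1 3.34. With miR-429, further distances were MAP7 2.25, ASPH 3.31, OVOL1 1.27, VIM 1.63, CDH2 0.83, ZEB1 1.60, ZEB2 2.18, SNAI2 2.24, TWIST1 0.55, KRT18 3.14, SPINT2 2.67 and SEC23A 1.14. With miR-429, to these add CXCL2 2.13, CXCL8 1.59, PATJ 2.25, PKP2 1.18, CLDN3 1.42, PPL 1.36, RPL18 2.58 and RPL35 2.28. The highest adjusted p of these genes was 0.0447, for CDH2.

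Whole lists differed between lines as well, here as the median over genes of the difference in log2 change. With miR-203a these were epithelial 0.95 (PC3 minus HEY), epithelial 0.67 (PC3 minus SKOV3), mesenchymal -0.13 (SKOV3 minus HEY) and EMT transcription factors -0.45 (PC3 minus HEY). Further miR-203a differences were published targets of miR-203a -0.26 (SKOV3 minus HEY), interferon response 0.62 (PC3 minus HEY), inflammatory cytokines 0.39 (SKOV3 minus HEY) and inflammatory cytokines 0.91 (PC3 minus HEY). Further miR-203a differences were ribosomal proteins 1.65 (PC3 minus HEY) and 1.81 (PC3 minus SKOV3). With miR-205 these were interferon response 3.79 (PC3 minus HEY) and 3.75 (PC3 minus SKOV3), and inflammatory cytokines 1.63 (PC3 minus HEY) and 0.90 (PC3 minus SKOV3). Further miR-205 differences were unfolded protein and integrated stress response 0.83 (PC3 minus HEY) and 0.93 (PC3 minus SKOV3), tight junction and desmosome 0.67 (PC3 minus HEY) and microRNA machinery -0.80 (PC3 minus SKOV3). Further miR-205 differences were ribosomal proteins -0.87 (SKOV3 minus HEY) and 1.21 (PC3 minus SKOV3). With miR-429 these were interferon response 0.33 (PC3 minus SKOV3), inflammatory cytokines 0.20 (PC3 minus SKOV3), ribosomal proteins -0.55 (SKOV3 minus HEY) and ribosomal proteins -0.60 (PC3 minus HEY). With an estimated correlation only the differences of the interferon response with miR-205 still passed the threshold, with adjusted p of 0.00661 and 0.00592.

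Signal also appeared in control probe sets that no comparison uses. DapX-3, which reports RNA of a Bacillus gene added before labelling, averaged 10.2 log2 units on the transfected SKOV3 arrays and at most 2.98 in the other 11 groups. BioB-3, which reports a control added at hybridisation, averaged 3.32 and 3.51 on arrays labelled untransfected HEY and SKOV3 and 9.52 on the others. These levels divide the arrays by more than the line or the treatment alone.

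The arrays labelled untransfected lacked the genes of the line on their label. Another labelling or hybridisation of these arrays would leave genes that PC3 lacks off, yet 0.0% of these genes were off on the arrays labelled untransfected PC3. The arrays labelled HEY and SKOV3 had alike control levels, yet the highest percent of SKOV3-specific genes on among those labelled SKOV3 (33.3) minus the lowest among those labelled HEY (83.3) was -50.0. Line-specific genes went opposite ways from untransfected to miR-NC. Higher in HEY and lower in PC3 were 45 of 45 HEY-specific genes. Higher in SKOV3 and lower in HEY were 74 of 84 SKOV3-specific genes. Higher in PC3 and lower in SKOV3 were 91 of 133 PC3-specific genes (68.4%). Their choice by transfected levels, miR-NC included, favours this. Over all genes called in both lines of a pair, 29.7% to 42.7% went opposite ways, so an effect of transfection shared by the lines stays open. Labels exchanged in a cycle (HEY to SKOV3, SKOV3 to PC3, PC3 to HEY) are a candidate explanation for the arrays labelled HEY and PC3, of which 6 of 6 matched the next line best by specific genes. Their groups also correlated best with it (0.935 and 0.961 at most, against 0.767 and 0.843 with the line on the label). For the arrays labelled SKOV3 the cycle stays open, since the values go both ways. Their specific genes matched PC3 best (66.2 to 69.3, against 50.6 to 51.8 for SKOV3, mean percent of specific genes on and absent genes off), but the group correlated better with SKOV3 than with PC3 groups (0.803 and 0.743 at most, 0.060 apart). Of genes PC3 lacks 95.4% were off there and 0% in transfected SKOV3. HOXB13 averaged 11.73 there and at most 8.19 in transfected PC3. CTNNA1, which PC3 lacks, averaged 4.45 there, at most 3.57 in transfected PC3 and at least 12.46 in transfected SKOV3. No transfected PC3 group shares their control levels, which may lower that correlation, and another line was not tested.

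Most genes were called in HEY with miR-205 and miR-429 and in PC3 with miR-203a and miR-205. A set of arrays apart from miR-NC in labelling or hybridisation is a candidate explanation, since changes by different miRNAs in HEY and PC3 correlated across genes at 0.644, 0.505 and 0.430. An effect of the transfected miRNA is a candidate explanation too: genes that fell at least 2-fold in SKOV3 with the same miRNA were lower more often than other genes in all 4 groups, with a smallest excess of 25.4 percentage points (84.6% against 59.1%, HEY miR-429). Both stay open, and how many of the calls each accounts for was not tested.

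Interferon-response genes rose with miR-205 in PC3. The control levels that set PC3 miR-205 and PC3 miR-203a apart from miR-NC do not account for it, since the list lay 2.75 log2 units higher with miR-205 than with miR-203a. An effect of miR-205 in every line is argued against by a median of -0.004 in SKOV3. A response of PC3 cells to this miRNA, or to this preparation of the precursor, stays open and was not tested.

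Other splits of the same arrays were tried for each count of changed genes. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each of these 15 comparisons only the real split gave as many genes. The real count and the highest of the other splits were, with each miRNA against miR-NC, HEY miR-203a 2052 and 4, SKOV3 miR-203a 1863 and 2, PC3 miR-203a 8754 and 16, HEY miR-205 10259 and 3 and SKOV3 miR-205 4001 and 0. They were also PC3 miR-205 7548 and 23, HEY miR-429 8854 and 37, SKOV3 miR-429 3443 and 1 and PC3 miR-429 7175 and 293. For the comparisons that use arrays labelled untransfected they were HEY miR-NC against untransfected 13002 and 341, SKOV3 miR-NC against untransfected 11345 and 1, PC3 miR-NC against untransfected 12019 and 4, untransfected SKOV3 against HEY 8275 and 1645, untransfected PC3 against HEY 11608 and 500 and untransfected PC3 against SKOV3 11945 and 1. The highest other counts, 1645 and 500, both involve the arrays labelled untransfected HEY, which differ among themselves. For the differences between lines, 100 splits within lines were compared, the real one and random ones. Only the real one gave as many genes: 7009 against a highest other of 6844 for miR-203a, 10862 against 9794 for miR-205, and 10375 against 10135 for miR-429. The highest other splits kept the real grouping in 2 of the 3 lines and so carry its effect. The 68, 73 and 71 splits that kept it in none gave at most 1, 1 and 4 genes.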

How the results depend on the processing

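The fits without the arrays labelled untransfected and with the other PC3 group as the control were chosen after seeing the data, the other alternatives before. The planned shift of genes with a seed site, and its 8-base alternative, was not run. Counts of changed genes were judged by total only, not by direction. Shifts and differences of the epithelial and mesenchymal lists and the interferon shift in PC3 with miR-205 were judged by direction and call. Results held in 504 refits without 1 array (18 reversed, 3 lost and 3 gained a call). Of 58 results 57 held with an intensity trend and robust prior, 56 with a stricter filter and 54 with no filter. With the mean of the gene's probe sets 53 held, with array medians subtracted 51 and with quantile normalization 50. With the replicate number as a block all 58 did. The numbers gave no pairing: arrays of different treatments that share a number correlated, after their group means were removed, at 0.023 in HEY, -0.001 in SKOV3 and 0.020 in PC3 on average. Arrays correlated best with their own number in 7, 6 and 10 of 15 cases. The interferon rise in PC3 with miR-205 kept direction and call under every alternative run for it.

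The untransfected control sets each group against arrays that lack the genes of its labelled line, and this shows in the values. Changed genes in HEY miR-203a came to 12803, SKOV3 miR-203a 11429, SKOV3 miR-205 11460, SKOV3 miR-429 11764 and PC3 miR-429 12764. The response to miR-203a differed between lines for 13963 genes, and genes changed alike in all 3 lines came to 2945 for miR-203a, 2568 for miR-205 and 3717 for miR-429. Among list shifts, epithelial HEY miR-203a (-1.86), epithelial SKOV3 miR-203a (-0.18), epithelial HEY miR-205 (-1.83), epithelial SKOV3 miR-205 (-0.26), epithelial HEY miR-429 (-1.61), epithelial SKOV3 miR-429 (-0.13), mesenchymal HEY miR-429 (0.67) and mesenchymal SKOV3 miR-429 (0.75) reversed. Now past the threshold were epithelial PC3 miR-429 (2.08) and mesenchymal SKOV3 miR-205 (1.28). Differences between lines that reversed were epithelial miR-205 SKOV3 minus HEY (0.83), epithelial miR-429 PC3 minus HEY (3.70), epithelial miR-429 PC3 minus SKOV3 (2.87), mesenchymal miR-203a SKOV3 minus HEY (0.18), mesenchymal miR-203a PC3 minus HEY (-1.12), mesenchymal miR-203a PC3 minus SKOV3 (-1.37) and mesenchymal miR-205 PC3 minus HEY (-0.70). Those now past the threshold were epithelial miR-203a SKOV3 minus HEY (0.81), epithelial miR-205 PC3 minus HEY (4.66), epithelial miR-205 PC3 minus SKOV3 (3.75), epithelial miR-429 SKOV3 minus HEY (1.76), mesenchymal miR-205 PC3 minus SKOV3 (-1.60) and mesenchymal miR-429 PC3 minus SKOV3 (-1.40). Of the named genes 105 kept direction and side of the threshold and 95 reversed, with these log2 changes. HEY miR-203a gave C16orf54 0.087, ITGB8 -3.77, SP4 2.02, CDH1 -5.02, ESRP1 0.011 and VIM -1.50. It also gave ZEB1 1.60, SNAI2 1.80, SOCS3 3.87, IFIT3 0.41 and CXCL8 0.53 in HEY miR-203a. SKOV3 miR-203a gave ITGB8 -1.52, PKIA -1.19, CDH1 -5.71, EPCAM -3.91, RAB25 -0.038, OVOL1 -0.89, ZEB1 2.68 and SNAI2 0.73. PC3 miR-203a gave RPL29 -1.19, RPL18 -2.25, THSD7A 0.65, RASSF6 2.96, OVOL1 2.70 and VIM -1.85. It also gave SNAI2 0.69, TWIST1 2.06, KRT7 -0.25, ATF4 -0.42 and RPS9 -2.65 in PC3 miR-203a. SKOV3 miR-205 gave PKIA -0.14, NARF -0.040, TMEM170B 0.42, CDH1 -5.35 and EPCAM -2.35. It also gave RAB25 -0.048, OVOL1 -0.43, VIM 0.54, ZEB1 1.32 and ZEB2 0.11 in SKOV3 miR-205. PC3 miR-205 gave SLC26A5-AS1 1.71, PCDHB16 0.58, NARF -0.91, KRT7 -0.95, MRPL27 -1.28, TMEM170B 0.045, KAT2B 0.36 and ESRP1 5.08. It also gave OVOL1 3.32, VIM -2.69, SNAI2 1.44, TWIST1 2.20, KRT8 -2.14, ITGA5 -0.51, RPL18 -3.63 and RPS9 -3.60 in PC3 miR-205. HEY miR-429 gave SNTG2-AS1 0.70, ITGB8 -4.60, GPM6A 0.82, CDH1 -4.84, EPCAM -6.24 and VIM -0.55. It also gave CDH2 2.60, ZEB2 4.64, TWIST1 3.96, SPINT2 -3.85 and RPL18 -1.66 in HEY miR-429. SKOV3 miR-429 gave CDH1 -1.54, EPCAM -0.13, ITGB8 -0.96, MAP7 -0.75, WIPF1 3.81, GPM6A 0.46 and ESRP1 -1.50. It also gave GRHL2 0.042, OVOL1 -0.73, VIM 0.56, FN1 3.51, ZEB1 0.54, CXCL2 2.26 and CXCL8 0.99 in SKOV3 miR-429. PC3 miR-429 gave GPM6A 0.12, RAB25 0.31, OVOL1 2.27 and SNAI2 0.69. HEY miR-205 gave CDH1 -5.21, EPCAM -6.67, GRHL2 -0.044, VIM -0.66 and CDH2 2.74. It also gave ZEB2 5.24, SNAI2 1.99, TWIST1 2.54, RPL18 -0.34 and RPS9 -0.21 in HEY miR-205.

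With the other PC3 group as the control, 3862 genes differed in either direction, and the values are by construction the difference between the 2 miRNAs. Of the named genes 29 kept direction and side of the threshold, 11 lost a call and 21 reversed. PC3 miR-205 gave PCDHB16 0.20, NARF -0.54, KRT7 -0.70, MRPL27 -0.42, CDH1 -0.011, GRHL2 -0.066, RAB25 -0.44, OVOL1 0.62 and VIM -0.84. It also gave FN1 0.32, ZEB1 0.31, ZEB2 0.91, SNAI2 0.76, TWIST1 0.14, KRT8 -0.28, RPL18 -1.37 and RPS9 -0.96 in PC3 miR-205. PC3 miR-203a gave PKIA -0.25, ITGB8 -0.003, EPCAM -0.33 and CDH2 -0.20.

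A 2-fold minimum left fewer genes by construction: HEY miR-203a (384), SKOV3 miR-203a (362), PC3 miR-203a (3260), HEY miR-205 (5186), SKOV3 miR-205 (768), PC3 miR-205 (2555), HEY miR-429 (3412), SKOV3 miR-429 (666), PC3 miR-429 (1602), SKOV3 miR-NC against untransfected (6126), PC3 miR-NC against untransfected (7228), untransfected SKOV3 against HEY (4032), untransfected PC3 against HEY (6975) and untransfected PC3 against SKOV3 (7423), and miR-203a (35), miR-205 (63) and miR-429 (34) in all 3 lines. A separate fit per line gave 1051 changed genes in HEY miR-203a, put the epithelial list in PC3 miR-429 (0.28) past the threshold and took the mesenchymal list in SKOV3 miR-429 (-0.10) below it. Without the arrays labelled untransfected, 629 genes changed alike in all 3 lines with miR-203a, and mesenchymal SKOV3 miR-429 (-0.10) lost its call. In that fit 227 named genes stayed the same and 17 passed the threshold anew: SNAI2 in HEY miR-203a (-0.63), EPCAM in SKOV3 miR-203a (0.63), CDH1 in PC3 miR-203a (0.88), GRHL2 in PC3 miR-203a (0.33), GRHL2 in HEY miR-205 (0.32), FN1 in HEY miR-205 (0.42), SNAI2 in HEY miR-205 (-0.44), CDH1 in SKOV3 miR-205 (0.75), CDH1 in PC3 miR-205 (0.87), SNAI2 in PC3 miR-205 (-0.32), TWIST1 in PC3 miR-205 (-0.26), ESRP1 in HEY miR-429 (0.68), CDH2 in HEY miR-429 (-0.26), CDH2 in SKOV3 miR-429 (0.57), ESRP1 in PC3 miR-429 (0.76), CDH2 in PC3 miR-429 (0.56) and ZEB2 in PC3 miR-429 (-0.34). Among these, CDH1 in SKOV3 miR-205 had both means near background. An estimated correlation changes no fold but ended the calls of epithelial PC3 miR-203a (0.90), epithelial PC3 miR-205 (0.64), epithelial HEY miR-429 (0.38) and mesenchymal SKOV3 miR-429 (-0.10), and of the differences epithelial miR-203a PC3 minus HEY (0.95), epithelial miR-203a PC3 minus SKOV3 (0.68) and mesenchymal miR-203a SKOV3 minus HEY (-0.13).

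Over all 22 lists, 26 of 198 shifts and 24 of 198 differences between lines were called. Calls lost/gained, for shifts and then differences, came to 1/8 and 2/6 with the mean of probe sets, 1/9 and 0/12 with no filter, 3/3 and 5/0 with a stricter filter (189 of each tested), 2/6 (shifts only) with a separate fit per line, 0/1 and 0/0 with the replicate block and 3/4 and 2/3 with quantile normalization. They came to 1/1 and 2/2 with array medians subtracted, 0/3 and 0/2 with an intensity trend and robust prior, 0/5 and 3/1 with no cross-hybridising probe sets, 2/8 and 0/5 with no arrays labelled untransfected, 18/37 and 14/50 with the untransfected control and 21/0 and 22/0 with an estimated correlation. In refits without 1 array they came to 4/13 and 9/12. With the mean of probe sets, published targets of miR-203a HEY miR-203a (-0.20), EMT transcription factors miR-203a PC3 minus HEY (-0.48) and microRNA machinery miR-205 PC3 minus SKOV3 (-0.69) lost a call. With a stricter filter, stress response PC3 miR-203a (0.60), published targets of miR-429 HEY miR-429 (-0.67), tight junction and desmosome PC3 miR-429 (0.30), inflammatory cytokines miR-203a PC3 minus HEY (1.02), stress response miR-205 PC3 minus HEY (0.83), tight junction and desmosome miR-205 PC3 minus HEY (0.68) and microRNA machinery miR-205 PC3 minus SKOV3 (-0.65) lost a call. With a separate fit per line, microRNA machinery SKOV3 miR-205 (0.19) lost a call. With quantile normalization, microRNA machinery SKOV3 miR-205 (0.048), tight junction and desmosome PC3 miR-429 (0.27) and microRNA machinery miR-205 PC3 minus SKOV3 (-0.70) lost a call. With array medians subtracted, tight junction and desmosome PC3 miR-429 (0.67), interferon response miR-429 PC3 minus SKOV3 (0.69) and inflammatory cytokines miR-429 PC3 minus SKOV3 (0.57) lost a call. With no cross-hybridising probe sets, inflammatory cytokines miR-203a SKOV3 minus HEY (0.40), EMT transcription factors miR-203a PC3 minus HEY (-0.45) and microRNA machinery miR-205 PC3 minus SKOV3 (-0.80) lost a call. With no arrays labelled untransfected, tight junction and desmosome PC3 miR-429 (0.26) lost a call.

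For the following alternatives the cause was not tested. Without probe sets that may cross-hybridise, epithelial HEY miR-203a (-0.011), mesenchymal SKOV3 miR-203a (-0.001) and mesenchymal PC3 miR-203a (0.037) reversed and epithelial PC3 miR-429 (0.28) passed the threshold. With the mean of the gene's probe sets, mesenchymal SKOV3 miR-203a (-0.044) and mesenchymal PC3 miR-203a (0.076) reversed, as did the differences mesenchymal miR-205 PC3 minus SKOV3 (0.002) and mesenchymal miR-429 SKOV3 minus HEY (-0.035), and epithelial PC3 miR-429 (0.046) passed the threshold. With no filter, mesenchymal SKOV3 miR-203a (-0.001) reversed, mesenchymal SKOV3 miR-429 (-0.11) lost its call, and epithelial PC3 miR-429 (0.23) and the difference epithelial miR-205 PC3 minus SKOV3 (0.37) passed the threshold. A stricter filter reversed mesenchymal SKOV3 miR-203a (-0.032) and ended the call of the difference epithelial miR-203a PC3 minus SKOV3 (0.51). Quantile normalization reversed mesenchymal SKOV3 miR-203a (-0.027) and the differences mesenchymal miR-203a PC3 minus HEY (-0.040) and mesenchymal miR-429 PC3 minus HEY (0.004). It put epithelial PC3 miR-429 (0.30) and mesenchymal PC3 miR-429 (-0.20) and the difference epithelial miR-429 PC3 minus SKOV3 (-0.52) past the threshold, and ended the calls of mesenchymal SKOV3 miR-429 (-0.13) and of the difference mesenchymal miR-203a SKOV3 minus HEY (-0.13). Array medians subtracted reversed mesenchymal HEY miR-205 (-0.014) and mesenchymal PC3 miR-429 (0.070) and the differences epithelial miR-429 PC3 minus HEY (0.23), mesenchymal miR-203a PC3 minus HEY (-0.060), mesenchymal miR-429 PC3 minus HEY (0.23) and mesenchymal miR-429 PC3 minus SKOV3 (0.34), and put epithelial miR-429 PC3 minus SKOV3 (-0.32) past the threshold. An intensity trend with a robust prior put the difference epithelial miR-429 PC3 minus SKOV3 (-0.69) past it.

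Single genes that reversed under these alternatives had small changes or several probe sets, and the cause was not tested. With the mean of the gene's probe sets: HEY miR-429 had ASPH -0.44. SKOV3 miR-203a had VIM -0.024. PC3 miR-203a had ESRP1 -0.14 and VIM -0.23. HEY miR-205 had VIM -0.65. SKOV3 miR-205 had FN1 -0.12. PC3 miR-205 had VIM -0.37. Untransfected PC3 against HEY had ESRP1 -0.46, VIM 1.22, FN1 0.16 and PAX8 -0.68. Untransfected PC3 against SKOV3 had VIM 1.81. With quantile normalization: HEY miR-203a showed EPCAM 0.004. SKOV3 miR-205 showed FN1 -0.043 and TWIST1 -0.065. SKOV3 miR-429 showed GRHL2 0.030, RAB25 0.020 and SNAI2 -0.045. PC3 miR-429 showed RAB25 0.45 and TWIST1 -0.092. Untransfected PC3 against SKOV3 showed SNAI2 -0.10. With array medians subtracted: HEY miR-203a came to EPCAM 0.014. PC3 miR-429 came to RAB25 0.39, VIM 0.25 and ZEB2 0.069. With the replicate block: Untransfected PC3 against HEY turned to ESRP1 -0.26 and FN1 0.22. Untransfected PC3 against SKOV3 turned to ERBB2 0.13. All named genes kept direction and side of the threshold with an intensity trend and robust prior and with no filter. Calls of named genes lost came to 10 with the mean of probe sets (ITGB8 PC3 miR-203a, LOX HEY miR-203a, LOX PC3 miR-203a, KRT7 SKOV3 miR-205, ASPH PC3 miR-429, VIM HEY miR-203a, VIM HEY miR-429, ZEB2 SKOV3 miR-429, SOCS3 HEY miR-203a and ZEB1 untransfected PC3 against HEY), 10 with a separate fit per line (PKIA HEY miR-203a, LOX HEY miR-203a, ITGB8 HEY miR-429, ESRP1 HEY miR-203a, FN1 HEY miR-203a, OVOL1 PC3 miR-203a, ESRP1 HEY miR-205, EPCAM HEY miR-429, TWIST1 HEY miR-429 and CXCL8 HEY miR-203a), 3 with the replicate block (RAB25 untransfected PC3 against HEY, RAB25 untransfected PC3 against SKOV3 and VIM untransfected PC3 against SKOV3), 6 with quantile normalization (ESRP1 HEY miR-203a, CDH2 SKOV3 miR-205, ZEB2 SKOV3 miR-429, EPCAM PC3 miR-429, RAB25 untransfected PC3 against SKOV3 and VIM untransfected PC3 against SKOV3) and 2 with array medians subtracted (TWIST1 HEY miR-429 and ZEB1 PC3 miR-429). RAB25 averaged 3.87 in PC3 miR-NC, below the median of all values (4.89), so its changes lie near background.

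Leaving out 1 array reversed a direction or changed a call as follows. Among lists, the mesenchymal list in SKOV3 miR-203a ran from -0.050 to 0.063, the mesenchymal list in PC3 miR-203a ran from -0.034 to 0.064, the mesenchymal list in SKOV3 miR-429 ran from -0.12 to -0.029, epithelial miR-203a SKOV3 minus HEY ran from -0.031 to 0.13, epithelial miR-429 PC3 minus SKOV3 ran from -0.78 to -0.63, mesenchymal miR-203a SKOV3 minus HEY ran from -0.18 to -0.10 and mesenchymal miR-203a PC3 minus HEY ran from -0.11 to 0.063. Arrays that decided a call were SKOV3 miR-NC replicate 2 for the mesenchymal list in SKOV3 miR-429, SKOV3 miR-203a replicate 3 and HEY miR-NC replicate 2 for the mesenchymal difference with miR-203a between SKOV3 and HEY, and PC3 miR-429 replicate 2, PC3 miR-NC replicate 1 and SKOV3 miR-NC replicate 2 for the epithelial difference with miR-429 between PC3 and SKOV3. Single genes that reversed follow. HEY miR-203a ranged over EPCAM -0.13 to 0.16, GRHL2 -0.16 to 0.026 and RAB25 -0.29 to 0.10. SKOV3 miR-203a ranged over RAB25 -0.10 to 0.14, OVOL1 -0.23 to 0.16 and ZEB1 -0.079 to 0.025. HEY miR-205 ranged over CDH1 -0.058 to 0.41. SKOV3 miR-205 ranged over GRHL2 -0.065 to 0.12, RAB25 -0.11 to 0.13 and FN1 -0.014 to 0.041. PC3 miR-205 ranged over OVOL1 -0.059 to 0.007. HEY miR-429 ranged over RAB25 -0.028 to 0.74. SKOV3 miR-429 ranged over RAB25 -0.21 to 0.036. PC3 miR-429 ranged over RAB25 -0.26 to 0.11. Untransfected SKOV3 against HEY ranged over GRHL2 -0.038 to 0.15, RAB25 -0.18 to 0.10, OVOL1 -0.073 to 0.13, CDH2 -0.54 to 0.47 and ZEB2 -0.036 to 0.20. Untransfected PC3 against HEY ranged over ESRP1 -0.29 to 1.64, GRHL2 -0.20 to 0.10 and FN1 -0.64 to 0.27. Untransfected PC3 against SKOV3 ranged over GRHL2 -0.27 to 0.031 and ERBB2 -0.23 to 0.14. Calls of named genes lost in some of their 6 refits, and in how many, were PKIA HEY miR-203a (6), PKIA PC3 miR-203a (2), ESRP1 HEY miR-203a (6), VIM HEY miR-203a (2), FN1 HEY miR-203a (6), OVOL1 PC3 miR-203a (3), FN1 PC3 miR-203a (5), TWIST1 PC3 miR-203a (2), CDH2 SKOV3 miR-205 (5), EPCAM PC3 miR-205 (2), RAB25 PC3 miR-205 (1), EPCAM HEY miR-429 (1), TWIST1 HEY miR-429 (4), ZEB2 SKOV3 miR-429 (3), EPCAM PC3 miR-429 (6), ESRP1 untransfected SKOV3 against HEY (1), RAB25 untransfected PC3 against HEY (2), PAX8 untransfected PC3 against HEY (2), RAB25 untransfected PC3 against SKOV3 (6) and VIM untransfected PC3 against SKOV3 (3).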
